A study of Mus musculus with 4 samples.

How the data were processed

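Germinal centre (GC) B cells are B cells that proliferate, mutate their antigen receptors and are selected in lymphoid follicles after immunization. They were sorted here by flow cytometry from mice immunized with sheep red blood cells 10 days earlier, per the labels. The mice carried a Myc reporter allele in which the endogenous Myc locus makes MYC fused to green fluorescent protein, and cells were sorted as MYC positive or MYC negative by that protein. RNA was extracted with Trizol, cleaned on a column with DNase treatment, amplified to biotin-labelled cRNA and hybridized to Illumina bead arrays, per the labels' protocols. There were 4 arrays, 2 per group. The labels number the replicates 1 and 2 in each group and call them biological replicates.

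The deposited probe signals are intensity values on a linear scale, not normalized, per the file headers. They cover 46235 probes and come with no detection p-value. The authors also deposited normalized intensity values. Within each array these have the same ranks as the raw signals (lowest rank correlation 1), and their sorted values differ between arrays by a median of 0.289% of their mean. The method behind them is not given in the sources used here. The value table of the series holds 45265 of the probes with the same normalized values (largest difference 0). The 970 probes it leaves out were taken as a stand-in for background. They are not described in the sources used here, and whether they are control probes is not known.

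Raw signals were background corrected with limma's normexp method with an offset of 50, quantile normalized between arrays and converted to log2 with R 4.3.3 and limma 3.58.1. Before the data were examined, a background correction and a filter based on detection p-values had been planned, with this procedure as the fallback where there are none. Probes whose mean log2 value lay in the upper 0.5 of the 45265 were tested (22632 probes). Genes were named through the platform annotation: 34875 probes had 1 gene symbol, 18 had several and 10372 are unnamed here. Symbols were matched by gene identifier to a RefSeq table of assembly GRCm38.p6, which changed 0 symbols and left 78 named probes unmatched. No genome build is named in the files, and no coordinates are given. Among the probes tested, 3629 are unnamed here and the rest name 12965 genes. A gene is represented by its brightest probe.

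Groups were compared per probe with limma's moderated linear model (lmFit and eBayes), without a block, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The fit with the replicate number as a block was the other fit planned beforehand. Samples with the same number carry the same tag in their titles and lay on the same chip, so the number marks at least a shared chip. Deviations of same-numbered samples from their group means correlated across the tested probes at r = 0.305. The MYC positive arrays were less alike than the MYC negative arrays (r = 0.911 against 0.976). MYC positive 2 correlated more with MYC negative 1 (0.933) and MYC negative 2 (0.935) than with MYC positive 1. Probes are not independent replicates. The same-numbered samples are called pair 1 and pair 2, and whether each pair came from 1 mouse is not stated. P-values measure only the spread between these samples. MYC positive samples were always at one position of the chip and MYC negative samples at the other, so position and group cannot be told apart.

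Before the data were examined, 24 gene lists were fixed. The 23 lists other than an X and Y chromosome check were tested with limma's camera at its preset correlation of 0.01, with p-values adjusted over the 23 lists. Camera with an estimated correlation and fry were run beside it. Camera asks whether a list lies above or below the other genes, and fry whether its genes move on balance one way. With an estimated correlation camera has only the 2 residual degrees of freedom of the 4 arrays. Each list's median was also set against 10000 random lists matched on mean signal. The matched percentile describes these arrays and is not a test across samples.

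The rule for named genes was also fixed beforehand. It takes Myc, the 12 genes with the largest called differences in each direction, up to 4 members of each list with the smallest p, the 4 most abundant members of each of the 3 lists of other cell types, and immunoglobulin constant genes and Gfp where present. The rule was fixed for the fit without block. Where fewer than 12 genes pass in a direction, it names those that pass and no others. That fit called no probe, so the rule named no gene by size of difference. The 12 genes per direction given here were instead taken from the fit with block, a choice made after the data were seen. A probe counted as above background where its raw signal exceeded the 95th percentile of the left-out probes on that array. For a probe below it on every array of a group, the fold is a lower bound. The bright group's mean is then set against the dim group's mean of, per array, the higher of the background level and the probe's own value.

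The tests were tested on simulated data with the 22632 probes, 2 arrays per group and 100 changed probes of each size. Without block, 5% of changes of 1 log2 unit and 92% of changes of 2 units were recovered, and 1 unchanged probe was called. With block, 44% and 99% were recovered, and 22 unchanged probes were called. In a simulated list test, a shift of 0.5 in the ribosome biogenesis list was called and 0 of 21 unshifted lists were. The simulated noise was drawn for each probe on its own, so this says nothing about false calls where genes of a list vary together. Alternatives covered background correction, normalization (cyclic loess, and log2 values scaled to a common array median, called median scaling below), the authors' values, the filter on dim probes, the variance model, the block and leaving out each array. The number of arrays limits the precision of every value.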

Results

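The 4 arrays measured RNA of GC B cells sorted with or without MYC protein, with 2 samples per group, to find how the GC B cells that hold MYC protein differ from those that do not. The MYC positive arrays were dimmer. In pair 1, 6166 probes (13.6%) of the MYC positive sample and 9786 (21.6%) of the MYC negative sample lay above background. In pair 2 the counts were 8435 (18.6%) and 12649 (27.9%). Quantile normalization gives every array the same distribution, so each difference reported is relative to the other probes of an array. Median scaling leaves the gap in brightness in place. It put the median difference of genes above background at -0.83 on the log2 scale. Values under it are given for the called lists that lay higher and for most genes described below as higher. The called lists that lay lower, and the genes described from them or among the largest called decreases, lay further below 0 under it. That follows from the gap in brightness and is no support for those calls. Differences are MYC positive minus MYC negative on the log2 scale, errors are SE from the fit with block unless stated, and n = 2 arrays per group.

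Relative to the other genes, the lists of MYC targets, ribosome biogenesis, metabolism, light zone and NF-kappaB genes lay higher in MYC positive cells, and those of GC identity, dark zone, MHC class II and cell cycle inhibitor genes lower. None of these 12 camera calls held with an estimated correlation (lowest adjusted p = 0.154), and the medians of all 8 higher lists lay below 0 under median scaling. Ccnd2, a D-type cyclin that drives entry into the cell cycle, was 7.58-fold higher (2.92 ± 0.24, and 1.56 under median scaling). Srm, which makes the polyamine spermidine, was 6.29-fold higher (2.65 ± 0.18, and 1.31 under median scaling). Mxd4, which competes with MYC for its partner MAX, was 5.89-fold lower (-2.56 ± 0.22). Lpp, a focal adhesion protein, was at least 3.69-fold lower, since neither MYC positive array lay above background. These genes passed limma's test with the pairs as a block, with adjusted p = 0.0200 for Ccnd2, Srm and Lpp and 0.0209 for Mxd4.

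Over all probes, the limma fit without block called 0 of 22632 at an adjusted p under 0.05. The smallest adjusted p was 0.0503, and 3493 probes had an unadjusted p under 0.05 (1373 higher and 2120 lower). With the pairs as a block, 430 probes of 329 named genes passed, 176 higher and 254 lower. All 430 went the same way in both pairs, but that fit takes disagreement between the pairs as its error, so this is no separate support. With block and median scaling 7613 probes passed, 29 higher and 7584 lower, so the share of higher calls went from 40.9% to 0.381%. Without block, leaving out MYC positive replicate 1 gave 177 calls, leaving out MYC positive replicate 2 gave 4484, and other choices of normalization or filter gave up to 911.

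The 12 named genes with the largest called increases in the fit with block included Ccnd2 and Srm. Ppa1, a pyrophosphatase, rose by 2.15 ± 0.21 (adjusted p = 0.0233), and Aprt, an enzyme of adenine salvage, by 1.78 ± 0.17 (adjusted p = 0.0233). Rrp1b and Nhp2, nucleolar proteins, rose by 1.94 ± 0.17 and 1.85 ± 0.17 (adjusted p = 0.0209 for each). Timm8a1, C1qbp and Atad3a, which encode mitochondrial proteins, rose by 1.87 ± 0.19, 1.81 ± 0.20 and 1.93 ± 0.17. Bcl2a1b and Bcl2a1d, survival genes of the BCL2 family induced by NF-kappaB, rose by 2.15 ± 0.17 and 2.02 ± 0.16, but they are near-identical copies whose probes may not tell them apart. Slpi, a secreted protease inhibitor, rose by 1.79 ± 0.26 (adjusted p = 0.0372). All 12 were smaller but above 0 under median scaling, and 6 of them were called higher there with block: Ccnd2, Srm, Ppa1 (0.71), C1qbp (0.80), Timm8a1 (0.56) and Bcl2a1b (0.59). The calls of Aprt (0.22), Rrp1b (0.44), Nhp2 (0.40), Atad3a (0.38), Bcl2a1d (0.45) and Slpi (0.36) were lost there. Tested probes of a gene did not all move alike: 1 of 3 for Ccnd2 gave 0.36, 1 of 3 for Srm gave 0.61, 2 of 4 for Rrp1b gave 0.33 and 0.87, and the other of Bcl2a1d gave 0.20.

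Among the 12 largest called decreases in the fit with block, besides Mxd4 and Lpp, Ypel3, which restrains growth, fell by 1.81 ± 0.18 (adjusted p = 0.0242). Pafah1b3, an enzyme of lipid metabolism, fell by 1.89 ± 0.24 and Anxa2, a membrane-binding annexin, by 1.81 ± 0.22. Klhl24, Snx29 and Fam214a fell by 1.78 ± 0.24, 1.78 ± 0.17 and 1.80 ± 0.19. Cyp4f18 fell by 1.77 ± 0.27, Rsph1 by 1.67 ± 0.23 and the linker histone gene H1f10 by 1.67 ± 0.29 (adjusted p = 0.0494). Ctdsp2, a phosphatase gene, was at least 2.14-fold lower, since neither MYC positive array lay above background. Other tested probes moved less: those of Mxd4 gave -0.63 and 0.27, the 5 of Lpp between -0.36 and 0.12, and those of Ypel3, Pafah1b3, Fam214a and Cyp4f18 gave -0.20, -0.40, -0.31 and -0.37. The other probes of Anxa2, Snx29 and H1f10 gave -0.73, -0.84 and -0.48.

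**Figure D1:**
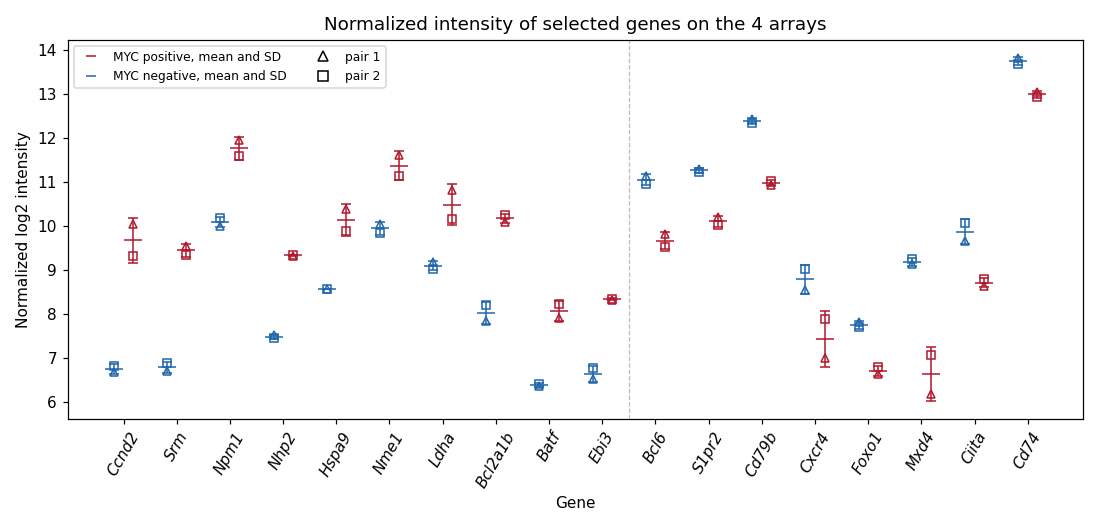
Normalized log2 intensity (y axis) of 18 genes (x axis) on the 4 arrays, MYC positive in red and MYC negative in blue, with triangles for pair 1, squares for pair 2, and the mean and SD of each group. The 10 genes left of the dashed line are higher and the 8 right of it lower in MYC positive cells of both pairs, but Hspa9, Nme1 and Ldha lie below 0 under median scaling (-0.03, -0.0073 and -0.18).

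After quantile normalization the canonical MYC targets had the highest median of the 23 lists, but under median scaling the mitochondrial chaperones and the T cell and NK cell and the myeloid and stromal markers lay above them. Of the 2 marker lists only 2 of 10 and 6 of 15 genes lay above background on at least 2 arrays. Against random lists matched on mean signal, MYC targets lay at percentile 100 under median scaling and the 2 marker lists at 92.6 and 77.15. Of the 21 measured MYC targets, 19 were higher in both pairs and none lower, with a median difference of 1.18 (1.20 in pair 1 and 1.08 in pair 2), against -0.07 under median scaling. Without block, 17 genes passed adjusted over the list alone, all higher, and 13 passed over all probes with block. Npm1, a nucleolar chaperone, rose by 1.67 ± 0.19 and the translation factor gene Eif5a by 1.61 ± 0.17, but under median scaling they lay at 0.22 and 0.02 and neither call held. Camera gave adjusted p = 4.09e-17, fry 0.00741 (0.0724 with block), and adjusted p = 0.154 with an estimated correlation.

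Genes of ribosome biogenesis followed. Of 32 measured, 28 were higher in both pairs and 1 lower, with a median of 0.80 against -0.07 under median scaling, where the arrays' gap in brightness remains. In this list 20 passed adjusted over the list alone, all higher, and 14 passed over all probes with block. Mrto4, needed for the large ribosomal subunit, rose by 1.68 ± 0.17, and Rrp12, an RNA-processing factor, by 1.52 ± 0.16. Under median scaling Mrto4 lay at 0.52 and was still called with block, and Rrp12 lay at 0.12 with no call. Gar1, a small nucleolar ribonucleoprotein, differed by 1.53 ± 0.16, but by -0.07 under median scaling and by -0.11 at its other probe. In this list camera had adjusted p = 4.09e-17, fry 0.00274 (0.0724 with block), and adjusted p = 0.154 with an estimated correlation. Under median scaling camera placed MYC targets and ribosome biogenesis above the other genes (adjusted p = 0.0157 each), although their medians lay below 0, and the calls of the other 6 higher lists were lost.

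Mitochondrial chaperones and one-carbon enzymes lay higher as well, with a median of 0.67 over 21 genes. Under median scaling it was -0.03 and the call was lost (camera adjusted p = 0.122), with the median at percentile 100 of random lists matched on mean signal. Of the 21, 17 were higher and 2 lower in both pairs. A total of 14 passed adjusted over the list alone, all higher, and 8 passed over all probes with block. The import chaperone Timm9 rose by 1.66 ± 0.21 (other probes 0.89 and -0.25) and the chaperonin partner Hspe1 by 1.23 ± 0.17, but under median scaling they lay at 0.16 and 0.14 and both calls were lost. The mitochondrial chaperone Hspa9 differed by 1.57 ± 0.19, with -0.03 under median scaling. The test by camera gave adjusted p = 1.75e-09, fry 0.00274 (0.0724 with block), and adjusted p = 0.154 with an estimated correlation.

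Of the metabolic lists, nucleotide synthesis had a median of 0.48 over 18 genes, glycolysis 0.44 over 13 and cytosolic tRNA synthetases 0.34 over 19. These turned to -0.23, -0.36 and -0.54 under median scaling, where all 3 calls were lost (camera adjusted p = 0.887, 0.405 and 0.151). Against random lists matched on mean signal, the 3 medians lay there at percentile 100, 99.55 and 99.45. In both pairs 14, 8 and 12 of their genes were higher and 4, 2 and 1 lower. Adjusted over the list alone 9, 4 and 2 genes passed, all higher, and 4, 2 and 1 over all probes with block. Nme2, a nucleoside diphosphate kinase, rose by 1.59 ± 0.18, but lay at 0.06 under median scaling with no call. Lactate dehydrogenase Ldha differed by 1.38 ± 0.19 but by -0.18 under median scaling, and the lysyl-tRNA synthetase Kars by 0.99 ± 0.18 but by -0.21, with 0.03 at its other probe. Camera gave adjusted p = 6.45e-06 for nucleotide synthesis, 0.00871 for glycolysis and 0.00191 for tRNA synthetases. In the same order fry gave 0.0341, 0.128 and 0.0398 (0.0724, 0.0948 and 0.186 with block), and the values were adjusted p = 0.200, adjusted p = 0.502 and adjusted p = 0.264 with an estimated correlation. Without MYC positive replicate 1 the glycolysis call was lost, and without MYC positive replicate 2 that of tRNA synthetases.

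Light zone genes, typical of the GC zone where B cells meet antigen and helper T cells, lay higher with a median of 0.55 over 19 genes (0.74 in pair 1 and 0.43 in pair 2), but -0.83 under median scaling. In both pairs 14 were higher and 2 lower. The NF-kappaB and CD40 response, which shares genes with it, had a median of 0.56 over 19 genes, with 13 higher and 4 lower in both pairs, but -0.27 under median scaling. Adjusted over the list alone 7 light zone genes passed, all higher, and 8 NF-kappaB genes were higher and 1 lower. Over all probes with block 4 of each passed, all higher, but Bcl2a1b, Bcl2a1d and Nfkbie were among the 4 of both lists. Only Batf in the light zone list and Ebi3 in the NF-kappaB list were not shared. The probes of Bcl2a1b and Bcl2a1d may not tell these near-identical genes apart. The transcription factor gene Batf rose by 1.68 ± 0.17 and the cytokine subunit gene Ebi3 by 1.69 ± 0.17, and under median scaling they lay at 0.77 and 0.55 and were called with block. Nfkbie, an inhibitor of NF-kappaB that it also induces, differed by 1.04 ± 0.17, but by -0.19 under median scaling and by -0.13 at its other probe. Camera gave adjusted p = 5.14e-06 for the light zone and 1.55e-04 for NF-kappaB, fry 0.0978 and 0.0807, and each had adjusted p = 0.340 with an estimated correlation. Both calls were lost under median scaling (camera adjusted p = 0.512 and 0.833), and that of NF-kappaB without MYC positive replicate 2. Under median scaling the 2 medians lay at percentile 99.65 and 100 of random lists matched on mean signal.

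GC B cell identity genes lay lower, with a median of -0.35 over 15 genes and 9 lower and 2 higher in both pairs. Of these, 5 passed adjusted over the list alone, all lower, and 3 over all probes with block. Bcl6, the repressor that GC B cells depend on, fell by 1.38 ± 0.17 (adjusted p = 0.0306 with block). Cd79b, a signalling chain of the B cell receptor, fell by 1.42 ± 0.17, and S1pr2, a receptor that keeps cells in the GC, by 1.15 ± 0.17, although 1 of its 3 tested probes gave 0.01. Pou2af1, a B cell coactivator, passed within the list (adjusted p = 0.00638) at -0.83 ± 0.17 but not over all probes with block (adjusted p = 0.0635). For the list, camera gave adjusted p = 7.52e-05, fry 0.00274 (0.0724 with block), and adjusted p = 0.210 with an estimated correlation.

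Dark zone genes, typical of the zone of proliferation and mutation, had a median of -0.34 over 9 genes, with 6 lower and 2 higher in both pairs. Here 4 passed adjusted over the list alone, all lower, and 3 over all probes with block. The chemokine receptor gene Cxcr4 fell by 1.35 ± 0.18, and the transcription factor genes Foxo1 and Foxp1 by 1.05 ± 0.17 and 1.03 ± 0.17, with -0.46 at the other probe of Foxp1. By camera the list had adjusted p = 0.00588, by fry 0.0994, and adjusted p = 0.321 with an estimated correlation. The call was lost without MYC positive replicate 1 and over probes above background on all 4 arrays.

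MHC class II presentation genes, which display antigen to helper T cells, had a median of -0.65 over 14 genes, with 9 lower and 1 higher in both pairs. Adjusted over the list alone 7 passed, all lower, and 2 over all probes with block. Ciita, the master regulator of these genes, fell by 1.15 ± 0.17 and H2-Ob, a modulator of peptide loading, by 1.19 ± 0.17. The invariant chain gene Cd74 passed within the list (adjusted p = 0.00847) at -0.76 ± 0.16, but not over all probes with block (adjusted p = 0.0743). The list had adjusted p = 5.48e-05 by camera, 0.0807 by fry, and adjusted p = 0.289 with an estimated correlation.

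Cell cycle inhibitors and quiescence genes had a median of -0.33 over 18 genes, with 10 lower and 3 higher in both pairs. Adjusted over the list alone 3 passed, all lower, and 4 over all probes with block. Besides Mxd4 and Foxo1, Trp53inp1, a target of p53, fell by 1.21 ± 0.17 (adjusted p = 0.0371 with block), with -0.39 at its other probe. Camera gave adjusted p = 0.00198, fry 0.0702, and adjusted p = 0.289 with an estimated correlation. The call was lost under median scaling (camera adjusted p = 0.143) and over probes above background on all 4 arrays. Under median scaling the median was -0.48, at percentile 24 of random lists matched on mean signal, against percentile 0.04 after quantile normalization.

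**Figure D2:**
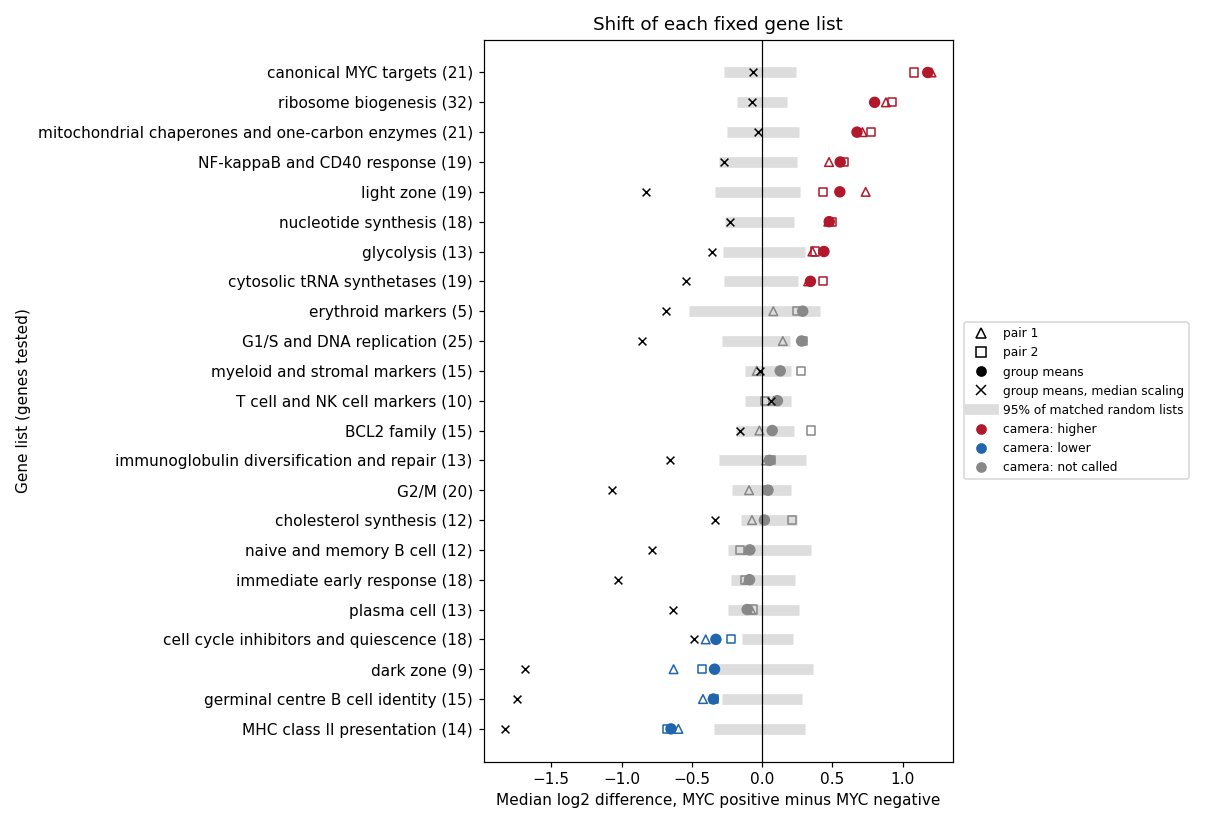
Median log2 difference (x axis, MYC positive minus MYC negative) of the 23 gene lists (y axis, with the number of genes tested), as group means (filled), in pair 1 (triangles), in pair 2 (squares) and under median scaling (crosses), with grey bars for 95% of random lists matched on mean signal after quantile normalization. The 8 lists in red were called higher by camera and the 4 in blue lower, but under median scaling the medians of all 8 red lists lie below 0.

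Lists of cell cycle phases did not pass at the settings reported. The 25 G1/S and DNA replication genes had a median of 0.28 (camera adjusted p = 0.0748), which turned to -0.85 under median scaling, where the list was called lower (adjusted p = 0.00293). That value is -0.02 relative to the genes above background, at percentile 94.3 of random lists matched on mean signal. Camera called the G1/S list higher with cyclic loess (0.25, adjusted p = 0.00829), with all probes of a gene (0.23, 0.0165), and over probes above background on 2 arrays (0.29, 0.0259) or 4 (0.34, 0.0416). With block it was also called higher above background on 2 arrays (0.0223) and without background correction (0.0480). The 20 G2/M genes had a median of 0.04 (adjusted p = 0.839), with camera's direction downward, and -1.07 under median scaling (adjusted p = 0.00272), at percentile 42.05 of matched lists. Among G1/S genes, Ccnd2 passed and Tyms, needed for thymidylate, differed by 0.97 ± 0.18 (adjusted p = 0.0551 with block), with -0.08 under median scaling and -0.07, 0.12, 0.38 and 0.43 at its other probes.

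The other programmes did not pass either. Immediate early response genes had a median of -0.09 (camera adjusted p = 0.194, but 0.0474 under median scaling), naive and memory B cell genes -0.09 (0.498), and plasma cell genes -0.11 (0.983, with a mean of 0.10). Cholesterol synthesis had 0.02 (0.983, camera's direction downward), immunoglobulin diversification and repair 0.05 (0.983), and the BCL2 family 0.07 (0.429), all of which lie below 0 under median scaling. Within the BCL2 family, Bcl2l11, which encodes the death-promoting BIM, differed by -1.27 ± 0.28 (adjusted p = 0.0779 with block, and 0.0386 over the list alone without block), with -0.08 and -0.01 at its other probes.

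Markers of other cell types did not pass as lists at the settings reported. Only 2 of 10 T cell and NK cell markers and 6 of 15 myeloid and stromal markers lay above background on at least 2 arrays, which limits what this shows. T cell and NK cell markers had a median of 0.11 (camera adjusted p = 0.922), myeloid and stromal markers 0.13 (0.219) and erythroid markers 0.29 (0.926), and the last 2 lie below 0 under median scaling (-0.02 and -0.68). Camera called myeloid and stromal markers higher with all probes of a gene (0.15, adjusted p = 0.0425) and above background on 2 arrays with block (0.38, 0.0384). Their median was 0.24 without MYC negative replicate 1. The lysozyme genes Lyz1 and Lyz2 differed by 0.95 ± 0.19 and 0.87 ± 0.28 with no call over all probes. Lyz1 passed over the list alone in the fit with block (adjusted p = 0.0280), but lay at -0.12 under median scaling, where Lyz2 lay at 0.27, and the other probe of Lyz2 gave 0.05. Ltf, at 0.17 under median scaling, was at least 1.41-fold higher with no call (adjusted p = 0.160 with block), since neither MYC negative array lay above background. Cd2, a T cell marker that B cells can also express, fell by 1.37 ± 0.22 (adjusted p = 0.0431 with block). The haemoglobin gene Hba-a1 differed by 0.33 ± 0.26, but by -0.72 under median scaling, and its level differed between the pairs (SD 1.65 in MYC negative cells).

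Myc transcript could not check the sort. Its 2 probes differed by 0.16 and 0.01, or by 0.18 and -0.06 under median scaling, and neither lay above background on a MYC positive array, so no fold is given. The Ighg1 probe, for an immunoglobulin constant gene, was at least 1.08-fold lower with no call (adjusted p = 0.564 with block), since neither MYC positive array lay above background. No probe of Gfp is named here. Of the genes given values above, Mxd4, Klhl24, Cyp4f18, H1f10, Foxo1, Trp53inp1, Bcl2l11 and Cd2 lay above background on 1 of the MYC positive arrays, and C1qbp, Batf and Lyz2 on 1 of the MYC negative arrays.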

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

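The 12 list calls and their directions were the same without background correction, with cyclic loess, the authors' values, the series table, no filter, the variance trend, all probes of a gene, an offset of 16, the left-out probes as negative controls, the filter of above background on 2 arrays and the replicate block. The block changed no list call by camera. With it fry called 0 lists against 6 without it, and an estimated correlation called 0 lists in either fit (lowest adjusted p = 0.154 without block and 0.432 with it), which uses only the 2 and 1 residual degrees of freedom. Without MYC positive replicate 1 the dark zone and glycolysis calls were lost, without MYC positive replicate 2 those of tRNA synthetases and NF-kappaB, and over probes above background on all 4 arrays those of cell cycle inhibitors and the dark zone. Leaving out 1 array gave 10 to 16 lists and median scaling 8 (2 higher and 6 lower).

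The count of probes, 0 without block, was 454 at an adjusted p under 0.10, 110 without background correction, 911 with cyclic loess, 129 with the authors' values and with the series table, 346 with no filter, 66 with a variance trend, 34 over probes above background on 2 arrays and 883 over those on 4. It stayed 0 with median scaling, an offset of 16, the left-out probes as negative controls, 1 probe per gene, and a minimum of 1 log2 unit. Leaving out 1 array gave 0 to 4484: 177 without MYC positive replicate 1, 4484 without MYC positive replicate 2 and 0 without either MYC negative array, where the lone sample is assumed to vary like the other group. With the replicate block the count was 430, and with block 1274 above background on 2 arrays, 1393 with no filter, 2760 with cyclic loess, 7613 with median scaling (29 higher), 698 with the authors' values and 223 without background correction. The filters test fewer probes, and for the other counts the cause was not tested. The larger Myc difference, 0.16, was 0.11 without background correction, 0.18 with median scaling, 0.14 with the authors' values and the series table, 0.38 with an offset of 16 and 0.085 with the left-out probes as negative controls, and 0.14 to 0.17 with 1 array left out. The block left these values as they were. Alternatives with an offset of 16, the left-out probes or a background level, and each combination of the block with another choice, were chosen after seeing the data. Normexp with an offset of 50 became the setting reported, and the planned detection filter was not run because there is no detection p. Leaving out an array in the fit with block leaves no residual degrees of freedom, so it was not run.

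Median scaling, with or without block, turned these list medians below 0: BCL2 family -0.16, canonical MYC targets -0.067, cholesterol synthesis -0.33, cytosolic tRNA synthetases -0.54, erythroid markers -0.68, G1/S and DNA replication -0.85, G2/M -1.07, glycolysis -0.36, immunoglobulin diversification and repair -0.65, light zone -0.83, mitochondrial chaperones and one-carbon enzymes -0.031, myeloid and stromal markers -0.018, NF-kappaB and CD40 response -0.27, nucleotide synthesis -0.23 and ribosome biogenesis -0.068. It also turned these genes below 0: Alas2 -0.75, Aldoa -0.55, Aurka -0.84, Creld2 -0.57, Ctps -0.20, Egr3 -0.72, Farsb -0.63, Fcer2a -1.05, Fdps -1.07, Gar1 -0.070, Gart -0.29, Hba-a1 -0.72, Hbb-b2 -0.68, Hsp90b1 -0.70, Hspa9 -0.031, Kars -0.21, Lars -0.92, Ldha -0.18, Lyz1 -0.12, Mcm10 -0.94, Mpeg1 -0.19, Nfkbie -0.19, Nme1 -0.0073, Pgk1 -0.36, Slc4a1 -0.32, Tpi1 -0.31, Trp53bp1 -1.02, Tyms -0.076, Ung -0.54 and Xrcc6 -0.95. The brightness gap that median scaling leaves in place accounts for its lower values by construction.

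With all probes of a gene the median was reversed for BCL2 family -0.011, cholesterol synthesis -0.026, G2/M -0.045, immunoglobulin diversification and repair -0.023 and plasma cell 0.034. With no filter, with or without block, the median was reversed for cholesterol synthesis -0.026 and naive and memory B cell 0.16. Without background correction, with or without block, the median was reversed for plasma cell 0.011. With the left-out probes as negative controls the median was reversed for plasma cell 0.088. Over probes above background on 2 arrays, with or without block, the median was reversed for naive and memory B cell 0.17 and T cell and NK cell markers -0.94. Over probes above background on 4 arrays the median was reversed for immunoglobulin diversification and repair -0.0098. Cyclic loess, with or without block, reversed Mfge8 0.0061. With 1 array left out the values ranged from -0.61 to 1.21 for Alas2, from -0.87 to 1.496 for Hba-a1, from -0.49 to 0.77 for Hbb-b2, from -0.055 to 1.38 for Il7r, from -0.28 to 0.021 for Klf1, from -0.39 to 1.498 for Slc4a1, from -0.088 to 0.14 for cholesterol synthesis, from -0.39 to 0.95 for erythroid markers, from -0.038 to 0.079 for G2/M, from -0.051 to 0.080 for immunoglobulin diversification and repair, from -0.34 to 0.082 for naive and memory B cell and from -0.095 to 0.081 for plasma cell. None of these lists was called at the settings reported. Called lower elsewhere were the T cell and NK cell list above background on 2 arrays with block (adjusted p = 0.0497, on 2 genes), immunoglobulin diversification and repair under median scaling with block (0.0401), and G2/M under median scaling (0.00272), and the BCL2 family was called higher above background on 4 arrays (0.0388). Without MYC negative replicate 1, G1/S and DNA replication (0.00295) and myeloid and stromal markers (0.0157) were called higher, and immediate early response (0.00460) and naive and memory B cell genes (0.0264) lower. G1/S and DNA replication was also called higher with cyclic loess, with all probes of a gene and over probes above background on 2 or 4 arrays. Camera called myeloid and stromal markers higher with all probes of a gene (adjusted p = 0.0425) and above background on 2 arrays with block (0.0384). The cause was not tested. Of 2257 gene values under the alternatives 71 were reversed, 1360 kept direction and side of the threshold, and 826 kept direction and passed. Of 574 list values 59 were reversed and 26 lost the call with the same direction. Depth limits all of this: between 13.6% and 27.9% of probes per array lay above background.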

Other observations

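The gene families described first were chosen after the data were seen, as were the tests of the MYC lists relative to genes of like signal, of chip position, of compression over both normalizations and of naive or memory cells.

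Gene families other than the fixed lists also lay apart from other genes, and camera's values describe them rather than test them independently. Some share genes with those lists. The translation initiation factors hold the MYC targets Eif5a and Eif4a1, and the RNA polymerase subunits hold Polr1a and Polr1b of ribosome biogenesis. Mitochondrial ribosomal proteins had a median difference of 0.38 over 73 genes, with 48 higher and 5 lower in both pairs (camera adjusted p = 2.32e-09), respiratory complex I subunits 0.38 over 33 (1.71e-05), and the TCP1 chaperonin, which folds actin and tubulin, 0.74 over 7 genes, all higher in both pairs (7.05e-05), but none of these calls held with an estimated correlation, and under median scaling these medians were -0.62, -0.87 and -0.42. Proteasome subunits (0.31 over 33), ATP synthase and cytochrome oxidase subunits (0.30 over 27), translation initiation factors (0.25 over 37), RNA polymerase I and III subunits (0.25 over 12) and cytosolic ribosomal proteins (0.19 over 56) were called higher too, and all had medians below 0 under median scaling. With an estimated correlation all 8 higher families had adjusted p = 0.332. Under median scaling ATP synthase and cytochrome oxidase and RNA polymerase I and III lay at percentile 87.6 and 88.55 of lists of like signal, and the other 6 at 99.4 or higher. Core histones had -0.17 (0.0153, and adjusted p = 0.682 with an estimated correlation), but -0.02 with cyclic loess, -0.40 in pair 1 and 0.11 in pair 2, and the median lay at percentile 7.90 of random lists matched on mean signal. Regulators of FOXO and PI3K signalling had a median of -0.42 over 10 genes and the MAX and MLX network -0.24 over 7, but these families hold Foxo1 and Mxd4, already seen to be lower, so no test is given for them. Interferon-induced genes (-0.03, 0.485), GIMAP GTPases (-0.36, 0.0842) and Kruppel-like factors (-0.02, 0.399, and 0.01 with cyclic loess) were not called.

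The first pattern is the higher MYC-target, ribosome biogenesis and mitochondrial chaperone lists. Before normalization, raw signals less each array's median over the left-out probes were compared within pairs. Of the lists' 67 genes, 14.9% (10 genes, exact 95% interval 7.40% to 25.7%) were higher on the MYC positive array of both pairs. Among the other 12898 genes the share was 11.6%. Over genes above background on at least 2 arrays it was 13.6% of 59 (exact 95% interval 6.04% to 24.98%) against 2.95% of 6329. These intervals treat genes as independent and do not measure the spread between samples. The lists stood out there before normalization, but few of their genes were higher. The direction of the rise stays open to how the dimmer arrays are corrected for. A loss of brightness that depends only on signal level would move genes of like signal alike. The lowest percentile of the 3 lists among matched random lists was 100 under both quantile normalization and median scaling. On these arrays that argues against such a loss as the source of their place relative to other genes. A loss that depends on other features of a probe or transcript was not tested and stays open. Position on the chip stays open, since 0 positions held both groups, and so does a change in total RNA per cell, which these arrays do not measure. A relative shift toward growth genes in MYC positive cells is therefore a hypothesis, and an absolute rise is not shown.

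The second pattern is the lower MHC class II and GC identity lists. Compression of bright probes on the dimmer arrays would lower other genes as bright, but the MHC class II median lay at percentile 0.05 and the GC identity median at 0.99 of 10000 random lists matched on mean signal. Under median scaling they lay at percentile 1.75 and 0.05 of 2000, so the argument against compression is weaker there for MHC class II and stronger for GC identity. Position on the chip stays open for these lists too, and a biological cause other than the sort was not tested.

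The third pattern is the higher light zone and NF-kappaB lists. Naive or memory B cells in the MYC positive gate may also carry such genes and would raise both lists, although the sort for GC B cells should remove them. The light zone list holds Fcer2a, Gpr183 and Ccr6, which are also in the naive and memory list. With these kept, the naive and memory genes above background on 2 arrays had a median of 0.17, against 0.55 for the light zone list. The 6 naive and memory genes outside the light zone list that lay above background on 2 arrays had a median of -0.25. That is -0.80 relative to the light zone list, which kept the shared genes (bootstrap SE 0.42 over genes). Over all 9 measured the gap was -0.96 (SE 0.38), but the added genes lay near background, so such cells stay open. Whether the lists reflect recent contact with helper T cells was not tested.

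Xist, the RNA of X inactivation, differed by -0.96 and -0.99 at 2 probes (adjusted p = 0.0494 and 0.0466 with block), and by -0.02 at another, which lay at 0.07 with cyclic loess. Under median scaling these 3 gave -2.50, -2.56 and -1.22. At the remaining probe of the 4 the signal was at least 1.19-fold lower (adjusted p = 0.136 with block), since neither MYC positive array lay above background. The 4 other nuclear-retained RNAs measured, of 9 listed, had a median of -0.17 and went both ways, with Tug1 at 0.67, Neat1 at least 1.03-fold and Kcnq1ot1 at least 1.21-fold lower, so the test left open whether nuclear RNAs were lower as a class.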
